A study of Mus musculus with 24 samples.

How the data were processed

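Liver RNA from 24 samples was sequenced with a stranded mRNA library kit, per the labels' protocols. Each file holds 1 value per gene locus in FPKM, fragments scaled to transcript length and to the fragments mapped, which the authors computed before deposit. The submitters' processing notes name HISAT2, Cufflinks, Cuffdiff and the mouse build mm10, with no versions, and how strand was treated is not given in the sources used here.

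Each file lists 23746 loci of 23284 symbols. The 708 loci whose symbols occur at several loci were kept as they stand, and 14 loci that the files mark as failed in any library were left out. Of 2446 loci with a median FPKM of 20 or more, 20 were at 0 in some library, so a 0 can be a failed estimate, and such genes are given per library. Values at low loci came in steps: 72.0% to 74.3% of the fragment numbers they imply lay within 0.05 of a whole number, where chance gives 10%. These steps gave each library's depth relative to the mean, but no total, so intervals of counting error cannot be given.

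Groups and replicate numbers were taken from the sample titles. Genes were kept where FPKM was at least 1 in at least 3 of the fitted libraries, which left 10452 genes in the acute, 10375 in the constitutive and 10682 in the joint fit. Values were tested as log2(FPKM + 1) with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend) in R 4.3.3, with 1 coefficient per group and no covariate. All 12 libraries of a model shared 1 estimate of the spread, and all 24 did for differences between models. The contrasts were knockout against control in each state, refed against fasted in each genotype, their interaction, and the difference between models. P-values are two-sided and Benjamini-Hochberg adjusted over all genes kept, and genes were called at 0.05. Fold changes on the log2(FPKM + 1) scale understate changes of low genes; folds without the word log2 are ratios of mean FPKM.

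Lists of genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of each contrast. camera compares a list with the other genes, and it was repeated with a correlation estimated from the data. Of 35 lists, 26 were pathways and 9 were markers of cell types other than hepatocytes. Of 429 list entries 413 were in the files, 5 of them under older symbols. Mitochondrially encoded genes and pancreatic acinar, neutrophil, lymphocyte and erythroid markers had fewer than 3 kept genes and could not be tested. Adipocyte markers were tested in 7 comparisons and cholangiocyte markers in 2, and neither passed in any. Marker lists shared no gene with other lists, while 24 genes were in more than 1 pathway list. Sets of genes chosen in one model were measured in the other with limma's fry, which tests whether a set moves one way. Overlaps were tested with Fisher's exact test (scipy 1.17.1; Python 3.11.15, pandas 2.3.3, data.table of version 1.17.8).

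Genes were named by a fixed rule: Foxo1; the 6 rising and 6 falling calls with the largest log2 change whose groups did not overlap, without predicted-gene symbols and loci of several genes; 10 genes of metabolism in every comparison; up to 4 called members of each list past its test or with 3 calls; and the leading calls of interactions and model differences. Groups of 3 or fewer calls were named in full. Some results that this rule covers are not reported here. Other members of lists were named after their values were seen. The groups, tests, lists, naming rule and the first set of alternatives for genes were fixed before seeing the data.

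That first set held a pseudocount of 0.1, no filter, median-of-ratios scaling, a fit of the compared groups alone or with array weights, the replicate number as a block, calls at 0.01, an estimated correlation for lists, and each library left out in turn. A term for deeper and shallower libraries, the 8 shallower acute libraries alone and the difference of refeeding effects between models were added after seeing the data. For each model result, 10 or 100 splits of the libraries were run, the real one included.

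Simulated data held 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. Pairwise comparisons found 40.3% to 56.7%, 70.1% to 88.1% and 90.9% to 100%. Interactions and model differences found 19.4% to 31.3%, 53.7% to 70.1% and 81.8% to 93.9%. Calls among unchanged genes were 2 to 10, and 0 of 34 unshifted lists passed. Lists of correlated genes were not simulated.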

Results

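Liver RNA was sequenced from C57BL/6 mice that lacked the transcription factor FoxO1 in hepatocytes, either constitutively or after acute deletion. In the constitutive model, a floxed Foxo1 allele was removed by a Cre recombinase under the albumin promoter (KO), and floxed mice without Cre served as wild type (WT). In the acute model, floxed mice received an adeno-associated virus with the hepatocyte-specific TBG promoter driving Cre (Cre) or green fluorescent protein (GFP), and livers were taken on day 21. Mice were fasted for 4 h, or fasted for 4 h and refed for 1 h. The 24 libraries fall into 8 groups of 3. The labels do not state that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

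Total depth is unknown, but steps between low values gave the libraries' relative depth. In the acute model, 1 library of each group was deeper than the rest (GFP fasted 3 at 1.36 times the mean, Cre fasted 1 at 1.22, GFP refed 3 at 1.44 and Cre refed 1 at 1.37), and the other 8 lay between 0.58 and 0.70. The constitutive libraries lay between 1.15 and 1.33. Acute counts and list results are also given over the 8 shallower libraries alone.

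Foxo1 itself (chromosome 3, 52268337 to 52350109, mm10) checked the labels. In acute livers its level was 0.323 ± 0.0975 against 4.47 ± 0.125 FPKM in knockout and control fasted mice (SD, n = 3 each) and 0.415 ± 0.136 against 6.16 ± 0.576 FPKM in refed mice. The log2 changes were -2.05 ± 0.10 and -2.34 ± 0.10 (SE), with adjusted p = 3.09e-06 and 7.19e-07. In constitutive livers the levels were 0.433 ± 0.0810 against 5.33 ± 0.973 FPKM when fasted and 0.415 ± 0.0244 against 5.67 ± 0.989 FPKM when refed, with log2 changes of -2.13 ± 0.13 and -2.23 ± 0.13 and adjusted p = 1.39e-05 and 8.49e-06. All 12 knockout libraries lay below all 12 control libraries, and each of these calls held with any library left out. The loss of Foxo1 did not differ detectably between models, by 0.083 ± 0.16 fasted (adjusted p = 0.953) and -0.11 ± 0.16 refed (adjusted p = 0.830).

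**Figure D1:**
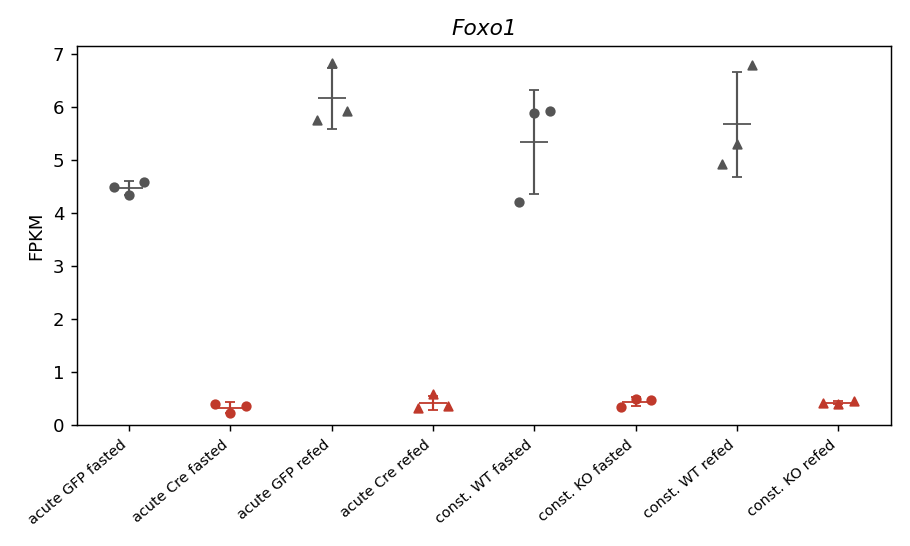
Foxo1 FPKM in each of the 24 libraries by group, with the group mean and SD. Knockout group means lie from 0.323 to 0.433 FPKM, and control group means from 4.47 to 6.16 FPKM.

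Fasted acute knockout and control livers were compared to ask which transcripts differ 21 days after deletion of FoxO1. Fgf21, which encodes a hormone secreted by the liver during fasting (chromosome 7, 45613890 to 45615490), rose 9.80-fold, at 3.23 ± 0.701 against 0.330 ± 0.176 FPKM (SD, n = 3 each). Slc37a4, the carrier that brings glucose-6-phosphate to glucose-6-phosphatase (chromosome 9, 44398176 to 44402965), fell 1.62-fold, at 72.9 ± 8.86 against 118 ± 1.52 FPKM. Cyp2b10, a drug-metabolising cytochrome P450 (chromosome 7, 25897664 to 25926624), fell 4.71-fold, at 2.71 ± 1.08 against 12.8 ± 2.75 FPKM. Of 10452 genes, 31 passed limma's test, 11 higher and 20 lower in the knockout.

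The log2 changes were 1.67 ± 0.19 for Fgf21 (SE; adjusted p = 0.00384), -0.70 ± 0.10 for Slc37a4 (0.0116) and -1.91 ± 0.28 for Cyp2b10 (0.0134). Other genes that rose were Erdr1 (2.06 ± 0.28), D0H4S114, now called Nrep (1.73 ± 0.30), the galectin gene Lgals1 (1.68 ± 0.24), Itih5 (1.46 ± 0.26) and the hepatic forkhead factor Foxa3 (0.88 ± 0.13). Other genes that fell were the cytochrome P450 Cyp2c38 (-1.94 ± 0.31), Prelid2 (-1.82 ± 0.24) and the translation inhibitor Eif4ebp3 (-1.75 ± 0.31). Cyp2c38 and Cyp2b10 belong to families of near-identical genes, so their levels are uncertain. The small nucleolar RNA Snord17 was at 0 in the 3 knockouts and at 6.17, 2.78 and 2.61 FPKM in controls, near the floor, so its call is uncertain. Calls held with any library left out for Foxo1, Fgf21 and Snord17. The call was lost without Cre fasted 2 for Prelid2 (adjusted p up to 0.0561), without GFP fasted 3 or Cre fasted 2 for Slc37a4 (p up to 0.0602) and without any of 3 to 5 libraries, GFP fasted 3 and Cre fasted 2 included, for Erdr1, Lgals1, D0H4S114, Itih5, Foxa3, Cyp2c38, Cyp2b10 and Eif4ebp3 (p up to 0.222). Counts of calls were 19 and 14 without GFP fasted 2 and 3 and 7 without Cre fasted 2, and 6 over the 8 shallower libraries, where Foxo1 and Erdr1 alone of those named so far stayed called.

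Of the genes fixed for every comparison, those that did not pass here were G6pc, the catalytic subunit of glucose-6-phosphatase, at 60.5 ± 15.5 against 178 ± 12.2 FPKM (-1.57 ± 0.34, adjusted p = 0.0873), the insulin receptor substrate Irs2 at 1.80 ± 0.161 against 4.24 ± 1.11 FPKM (-0.88 ± 0.17, 0.0611), Pck1 (-0.90), Ppargc1a (-0.52), Igfbp1 (-0.56), Cyp8b1 (-0.37), Cyp7a1 (0.29) and Srebf1 (-0.14), the last 6 with SE from 0.17 to 0.71 and adjusted p from 0.239 to 0.871.

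By gene list, genes of lipoproteins and lipid export were lower in fasted acute knockout livers (15 of 20 below 0, median -0.28, adjusted p = 9.98e-05, p = 0.0274 with estimated correlation). Of 15 lists past the test, it alone also passed with estimated correlation. None of its 20 members passed over all genes, and 6 fell adjusted over the list alone, among them the lipin Lpin1 (-1.32), the HDL receptor Scarb1 (-0.58) and hepatic lipase Lipc (-0.46). Gluconeogenic genes were lower (9 of 13 below 0, median -0.52, adjusted p = 0.00181, p = 0.294 with estimated correlation). Slc37a4 was called, and 6 of 13 members were lower adjusted over the list alone, including G6pc, Pck1 and Ppargc1a. Glucocorticoid-responsive genes were lower (9 of 10 below 0, median -0.62, adjusted p = 0.000755, p = 0.294 with estimated correlation). No member was called, and 5 were lower adjusted over the list alone, among them Per1 (-1.14), Sgk1 (-0.48) and Tat (-1.15). Circadian clock genes were lower (15 of 15 below 0, median -0.16, adjusted p = 0.00231, p = 0.294 with estimated correlation), with 0 members past over all genes or adjusted over the list alone. Glucose uptake, glycolysis and glycogen genes were lower as a list (11 of 15 below 0, median -0.16, adjusted p = 0.00659, p = 0.299 with estimated correlation). Adjusted over the list alone, 4 of them fell and 1 rose. The FoxO1 target list was lower (11 of 17 below 0, median -0.26, adjusted p = 0.0133, p = 0.294 with estimated correlation). None was called, and 7 were down and Pdk4 up adjusted over the list alone. This result was lost without GFP fasted 1 or Cre fasted 1 (0.0938 to 0.133), and over the shallower libraries (adjusted p = 0.140).

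Immediate early genes, which respond first to growth and stress signals, were higher (10 of 11 above 0, median 0.55, adjusted p = 0.000218, p = 0.294 with estimated correlation). No member was called, and Fos (1.13), Egr1 (1.69), Jun (1.41) and Klf6 (0.52) were higher adjusted over the list alone. Targets of PPARα, the receptor that drives fatty acid oxidation and ketogenesis, were higher (19 of 24 above 0, median 0.14, adjusted p = 0.000344, p = 0.294 with estimated correlation). Fgf21 was called, and 4 were up and Cyp4a10 down adjusted over the list alone. Cell cycle genes (4 of 4 above 0, median 0.29, adjusted p = 0.0145, p = 0.294 with estimated correlation) were also higher, with Pcna alone passing over the list alone. Male-biased, cholesterol synthesis, fatty acid synthesis, oxidative stress and interferon response genes were higher too (adjusted p from 0.00289 to 0.0399, or p from 0.357 to 0.611 with estimated correlation). None of their members was called, and Srxn1 alone passed adjusted over its list alone. Each result was lost without some library: male-biased without GFP fasted 1 or Cre fasted 2 (0.0897 to 0.0938), cholesterol without GFP fasted 3 (0.584) and fatty acid without GFP fasted 2 or 3 or Cre fasted 1 (0.0996 to 0.150). Oxidative stress was lost without GFP fasted 2 or Cre fasted 3 (0.0834 to 0.0856) and interferon without GFP fasted 2 or 3 or Cre fasted 2 or 3 (0.0716 to 0.315). Over the shallower libraries cholesterol (0.408) and fatty acid genes (0.243) did not pass. Among markers of other cell types, endothelial markers were lower (8 of 8 below 0, median -0.54, adjusted p = 0.000344, p = 0.299 with estimated correlation). None was called, and Oit3 (-1.04) was lower adjusted over the list alone.

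Refed acute knockout and control livers were compared to ask which differences are present 1 h after feeding. Cyp2b10 fell 12.8-fold, at 0.799 ± 0.436 against 10.2 ± 3.53 FPKM (SD, n = 3 each), and the call held with any library left out. Vnn1, a pantetheinase and PPARα target (chromosome 10, 23894688 to 23905343), fell 2.07-fold, at 16.8 ± 2.35 against 34.9 ± 1.04 FPKM, and Pigr, the receptor that carries IgA across epithelia (chromosome 1, 130826684 to 130852249), fell 1.69-fold, at 223 ± 13.1 against 376 ± 46.9 FPKM. Hes6 (chromosome 1, 91411483 to 91413222) rose 1.72-fold, at 68.0 ± 0.785 against 39.5 ± 2.88 FPKM. limma called 11 of 10452 genes, 5 higher and 6 lower.

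The log2 changes were -2.61 ± 0.28 for Cyp2b10 (SE; adjusted p = 0.00422), -1.02 ± 0.14 for Vnn1 (0.0219), -0.75 ± 0.10 for Pigr (0.0219) and 0.77 ± 0.11 for Hes6 (0.0272). Slc22a30 (0.62 ± 0.085) also rose, and Nlrp12 (-1.48 ± 0.23) and Tbc1d8 (-0.84 ± 0.13) fell. LOC622167 was higher, at 1.87, 2.13 and 2.79 FPKM in the knockout against 0.157, 0 and 0.149 in the controls. Calls were lost without any of 4 to 5 libraries, GFP refed 3 and Cre refed 1 and 3 included, for LOC622167, Hes6, Slc22a30, Nlrp12, Vnn1, Pigr and Tbc1d8 (adjusted p up to 0.163). Counts were 66, 5 and 4 without GFP refed 1, 2 and 3 and 5, 7 and 3 without Cre refed 1, 2 and 3, and 5 over the 8 shallower libraries, where Foxo1 alone of the genes named so far stayed called (Cyp2b10 had adjusted p = 0.160). These fixed genes did not pass (SE from 0.17 to 0.71 and adjusted p from 0.196 to 0.983): Ppargc1a -0.68, Pck1 -0.67, Srebf1 0.51, Irs2 0.30, Cyp8b1 -0.41, Igfbp1 -0.71, Cyp7a1 -0.11, G6pc -0.056 and Fgf21 -0.045.

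Lipoprotein and lipid export genes were lower in refed as in fasted acute knockout livers (18 of 20 below 0, median -0.26, adjusted p = 1.39e-05, p = 0.0194 with estimated correlation). Of 9 lists past the test here, again it alone passed with estimated correlation. Adjusted over the list alone 8 fell, among them Lpin2 (-0.70), Scarb1 (-0.44) and Apom (-0.52), while the cholesterol exporter Abca1 rose (0.39). Gluconeogenic genes were lower (13 of 13 below 0, median -0.21, adjusted p = 5.04e-05, p = 0.296 with estimated correlation), and Ppargc1a and Slc37a4 were lower adjusted over the list alone. PPARα targets were lower (19 of 24 below 0, median -0.12, adjusted p = 3.03e-05, p = 0.296 with estimated correlation), with Vnn1 called and 3 lower adjusted over the list alone. Heat shock genes (7 of 8 below 0, median -0.43, adjusted p = 5.51e-05, p = 0.320 with estimated correlation) and glucocorticoid-responsive genes (10 of 10 below 0, median -0.53, adjusted p = 0.000307, p = 0.296 with estimated correlation) were lower. Adjusted over each list alone, 4 of 8 heat shock genes, led by Hspa1b (-1.17), and Fkbp5 (-1.03) were lower. Fatty acid synthesis genes were higher (14 of 16 above 0, median 0.28, adjusted p = 0.000842, p = 0.296 with estimated correlation), with 0 members past either way. Genes known to be more active in male livers were higher (12 of 13 above 0, median 1.29, adjusted p = 1.39e-05, p = 0.296 with estimated correlation). Adjusted over the list alone 6 were higher, including the bile acid hydroxylase Cyp7b1 (2.25) and Hsd3b5 (3.48). Female-biased genes were lower (5 of 6 below 0, median -1.42, adjusted p = 0.00501, p = 0.403 with estimated correlation). This result was lost without GFP refed 2 (0.134) and over the shallower libraries (0.191). Pericentral hepatocyte genes were lower (7 of 11 below 0, median -0.17, adjusted p = 0.0281, p = 0.338 with estimated correlation). Cyp2e1 and Glul were lower adjusted over the list alone, and the result was lost without GFP refed 1 or 2 or Cre refed 1 or 2 (0.0508 to 0.196). Apart from Vnn1, 0 members of these lists were called over all genes.

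Refeeding of acute control livers gave the response to 1 h of food where FoxO1 is present. Irs2 (chromosome 8, 10986964 to 11008430) fell 5.42-fold, at 0.782 ± 0.251 against 4.24 ± 1.11 FPKM (SD, n = 3 each). Tsku, which encodes a secreted liver protein (chromosome 7, 98350668 to 98361328), rose 5.48-fold, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275631), rose 3.40-fold. limma called 686 of 10452 genes, 503 higher and 183 lower after refeeding, or 262 higher and 308 lower when libraries were scaled by the median of ratios.

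The log2 changes were -1.55 ± 0.17 for Irs2 (SE; adjusted p = 0.00125), 2.54 ± 0.35 for Tsku (0.00321) and 1.64 ± 0.25 for Cyp7a1 (0.00469). D0H4S114 (2.42 ± 0.30), the glycolytic regulator Pfkfb3 (1.54 ± 0.23), the glycogen-targeting subunit Ppp1r3b (1.47 ± 0.25), the insulin signalling genes Pik3r1 (1.08 ± 0.094) and Socs2 (1.5 ± 0.25) and the pseudogene Serpina4-ps1 (3.60 ± 0.83) also rose. The ephrin Efna1 (-2.06 ± 0.29), the stress-induced Akt inhibitor Trib3 (-1.82 ± 0.20) and the early response factors Egr1 (-1.87 ± 0.45) and Nr4a1 (-1.77 ± 0.37) fell. Foxo1 itself rose by 0.39 ± 0.10 (adjusted p = 0.0441). The small nucleolar RNAs Snora31 (230, 181, 54.5 FPKM refed), Snora43 (35.9, 18.8, 34.1) and Snora23 (5.23, 5.48, 2.48) were at 0 in fasted libraries. Snora78 (12.1, 10.9, 5.13 FPKM fasted) and Snord17 were at 0 refed. These calls are uncertain, with Snora23 and Snora78 near the floor. Igfbp1 (-2.33), Fgf21 (0.61), G6pc (-0.67), Cyp8b1 (-0.41), Pck1 (-0.32), Ppargc1a (0.11) and Srebf1 (-0.0029) did not pass (SE from 0.17 to 0.71 and adjusted p from 0.0736 to 0.995). Calls were lost without any of 3 to 6 libraries for Foxo1, Snora78, Serpina4-ps1, Egr1, Nr4a1, Snora31, Cited2, Hal, Lgr5, Snora43, Junb and Xbp1 (adjusted p up to 0.135). Counts were 298, 344 and 340 without GFP fasted 1, 2 and 3 and 345 and 345 without GFP refed 1 and 2. Over the shallower libraries 215 were called, and the calls of Foxo1, Snora31, Snora43, Serpina4-ps1, Tsku, Egr1, Cited2, Ppp1r3b, Cyp27a1, Abcb11, Xbp1, Per2 and Lgr5 were lost (adjusted p up to 0.159).

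Ribosome biogenesis genes rose in refed acute controls (15 of 15 above 0, median 0.51, adjusted p = 1.33e-08, p = 0.107 with estimated correlation). Of these, 8 were called and 12 were higher adjusted over the list alone, for example Nop2 (1.15), Nop56 (1.10) and Nop58 (1.37). Heat shock genes rose (8 of 8 above 0, median 1.17, adjusted p = 5e-08, p = 0.196 with estimated correlation). Of 8 genes, 7 were called and as many passed adjusted over the list alone, led by Hspa1b (1.94) and Hsph1 (1.71). FoxO1 targets were lower (13 of 17 below 0, median -0.21, adjusted p = 0.000423, p = 0.107 with estimated correlation). Irs2 and Cited2 were called, and 3 were lower adjusted over the list alone. Urea cycle genes (12 of 15 below 0, median -0.095, adjusted p = 0.00916, p = 0.471 with estimated correlation) and periportal genes (9 of 10 below 0, median -0.16, adjusted p = 0.0108, p = 0.236 with estimated correlation) were lower. In both the histidine-degrading enzyme Hal (-0.74) was the one member past over all genes and adjusted over the list alone. The urea cycle result was lost over the shallower libraries (0.0872). Bile acid genes were lower as a list (9 of 12 below 0, median -0.22, adjusted p = 0.0135, p = 0.136 with estimated correlation). Cyp7a1 rose while Cyp27a1 (-0.50) and the export pump Abcb11 (-0.42) fell, the same 3 adjusted over the list alone. That result was lost without GFP fasted 2 or GFP refed 3 (0.0501 to 0.0783). Unfolded protein response genes were higher (15 of 15 above 0, median 0.42, adjusted p = 0.0135, p = 0.590 with estimated correlation). Xbp1 (0.58) passed over all genes and adjusted over the list alone, and the result was lost without GFP fasted 3 or GFP refed 2 (0.0740 to 0.0861).

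Immediate early, clock, pericentral and xenobiotic genes were lower as lists in refed acute controls (adjusted p from 0.0135 to 0.0455, or p from 0.359 to 0.636 with estimated correlation). The members called were Egr1 and Junb (-1.52), Per2 (0.83), Cry2 (-0.82) and Nr1d1 (-1.66), and Cyp27a1 and Lgr5 (-0.58). Adjusted over each list alone 2, 2, 3 and 0 members were lower. The immediate early result was lost without GFP fasted 1 or GFP refed 3 (0.0889 to 0.125) and with scaling (0.0786), clock without GFP fasted 1, 2 or 3 or GFP refed 1 or 2 (0.0553 to 0.0740) and with scaling (0.131). The pericentral result was lost without GFP refed 3 (0.388) and over the shallower libraries (0.385), and xenobiotic without GFP fasted 1 or 3 or GFP refed 2 or 3 (0.0608 to 0.0969), over the shallower libraries (0.0872) and with scaling (0.0809).

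Refeeding of acute knockout livers gave the response to food where FoxO1 is absent. Egr1 fell 12.9-fold, at 1.93 ± 0.709 against 24.9 ± 7.33 FPKM (SD, n = 3 each), and Fgf21 fell 3.35-fold, at 0.966 ± 0.296 against 3.23 ± 0.701 FPKM. Ppp1r3b (chromosome 8, 35375741 to 35388137) rose 3.87-fold, at 45.8 ± 1.94 against 11.8 ± 4.41 FPKM, Pfkfb3 (chromosome 2, 11471431 to 11553929) 4.77-fold and the lipin Lpin1 (chromosome 12, 16535669 to 16589770) 3.56-fold. limma called 569 of 10452 genes, 449 higher and 120 lower, or 189 higher and 175 lower with median-of-ratios scaling. Over the 8 shallower libraries 6 genes were called, Lpin1 and Rhbg alone of those named here (adjusted p up to 0.250 for the others).

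The log2 changes were -3.14 ± 0.45 for Egr1 (SE; adjusted p = 0.00737), -1.10 ± 0.19 for Fgf21 (0.0137), 1.92 ± 0.25 for Ppp1r3b (0.00567), 1.72 ± 0.23 for Pfkfb3 (0.00596) and 1.72 ± 0.24 for Lpin1 (0.00614). Tsku (1.99 ± 0.35), Cyp7a1 (1.25 ± 0.25), Prelid2 (1.52 ± 0.24) and Serpina4-ps1 (3.69 ± 0.83) also rose, as did the lipogenic genes Thrsp (0.95 ± 0.16), Elovl6 (1.04 ± 0.22), Fasn (0.86 ± 0.18) and Acacb (0.70 ± 0.18) and the pyruvate kinase gene Pklr (0.98 ± 0.23). Jun (-1.91 ± 0.40), Junb (-1.80 ± 0.38), the stress-induced Gdf15 (-1.84 ± 0.43), asparagine synthetase Asns (-1.72 ± 0.45) and Osgin1 (-1.54 ± 0.32) fell. Igfbp1 (-2.48), Srebf1 (0.65), G6pc (0.85), Irs2 (-0.36), Cyp8b1 (-0.46), Foxo1 (0.10), Pck1 (-0.10) and Ppargc1a (-0.050) did not pass (SE from 0.10 to 0.71 and adjusted p from 0.0634 to 0.883). The call was lost without Cre fasted 2 for Fgf21, Prelid2, Thrsp and Bag3 (adjusted p up to 0.0627), without Cre fasted 2 or Cre refed 1 for Tsku and Vnn1 (p up to 0.0669) and without any of 3 to 6 libraries, Cre fasted 2 and 3 included, for Cyp7a1, Serpina4-ps1, Acacb, Jun, Oit3, Pdk4, Elovl6, Fasn, Pklr, Junb, Gdf15, Dcn, Asns, Hyou1, Pecam1, Osgin1 and Rhbg (p up to 0.153). Counts were 298, 57 and 196 without Cre fasted 1, 2 and 3 and 134 and 139 without Cre refed 1 and 2.

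Immediate early genes fell in refed acute knockout livers (11 of 11 below 0, median -0.82, adjusted p = 2.21e-09, p = 0.133 with estimated correlation), and 5 were called and 7 lower adjusted over the list alone. PPARα targets were lower (24 of 24 below 0, median -0.20, adjusted p = 3.03e-09, p = 0.133 with estimated correlation). Fgf21, Vnn1 (-0.78) and Pdk4 (-1.37) were called, and as many passed adjusted over the list alone. Ribosome biogenesis genes rose (15 of 15 above 0, median 0.48, adjusted p = 9.06e-08, p = 0.133 with estimated correlation). Of these, 9 were called and 10 passed adjusted over the list alone, for example Nop56 (1.09) and Nolc1 (1.11). Heat shock genes rose (8 of 8 above 0, median 0.75, adjusted p = 0.000650, p = 0.416 with estimated correlation), and 3 were called and 6 passed adjusted over the list alone, among them Bag3 (0.96). Unfolded protein response genes rose (14 of 15 above 0, median 0.53, adjusted p = 0.00122, p = 0.443 with estimated correlation). Hyou1 (1.12) was called, and 10 passed adjusted over the list alone. FoxO1 targets were lower (12 of 17 below 0, median -0.19, adjusted p = 0.00255, p = 0.133 with estimated correlation), with Pdk4 called and 2 past adjusted over the list alone. Pericentral genes were lower (10 of 11 below 0, median -0.13, adjusted p = 0.000650, p = 0.134 with estimated correlation), with the ammonium transporter Rhbg (-0.92) called and 2 past adjusted over the list alone. Endothelial markers were higher (8 of 8 above 0, median 0.75, adjusted p = 0.00118, p = 0.443 with estimated correlation). Oit3 (1.07) and Pecam1 (0.78) were called, and 7 of 8 passed adjusted over the list alone.

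Stellate cell and fibroblast markers were higher in refed acute knockout livers (7 of 7 above 0, median 0.40, adjusted p = 0.0424, p = 0.581 with estimated correlation). Dcn (0.94) was called and 2 passed adjusted over the list alone, and the result was lost without Cre fasted 2 or 3 or Cre refed 1 or 2 (0.0570 to 0.117). Xenobiotic genes (11 of 16 below 0, median -0.13, adjusted p = 0.00881, p = 0.501 with estimated correlation; lost without Cre fasted 3 or Cre refed 1 (0.0544 to 0.104)) and urea cycle genes (9 of 15 below 0, median -0.061, adjusted p = 0.0445, p = 0.581 with estimated correlation; lost without Cre fasted 3 or Cre refed 2 or 3 (0.0645 to 0.372)) were lower, with 0 members past either way.

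The acute knockout by refeeding interaction asked whether the response to food differed between knockout and control. Prelid2 rose on refeeding in the knockout and fell in controls, with a difference of 3.28 ± 0.34 on the log2 scale (SE; adjusted p = 0.00527). Gm4956, a predicted gene (chromosome 1, 21285246 to 21298312), differed by 2.73 ± 0.23 (0.00128). Snord17 differed by 2.21 ± 0.29 (0.0349), which was listed at 0 in every acute library but the 3 fasted controls. These 3 were the genes that limma called, all of them higher. The call was lost without Cre fasted 2 or 3, GFP refed 1, 2 or 3 or Cre refed 1, 2 or 3 for Snord17 (adjusted p up to 0.142), and the count was 9 without Cre fasted 1, and 6 over the shallower libraries, where Gm4956 alone of the 3 stayed called. PPARα targets had a lower refeeding change in the knockout (24 of 24 below 0, median -0.29, adjusted p = 4.39e-12, p = 0.164 with estimated correlation). No member was called, and Vnn1 (-1.39) and Fgf21 (-1.71) were lower adjusted over the list alone. Immediate early genes (11 of 11 below 0, median -0.85, adjusted p = 9.78e-05, p = 0.462 with estimated correlation) and heat shock genes (6 of 8 below 0, median -0.49, adjusted p = 0.000112, p = 0.462 with estimated correlation) were lower too, with 0 and 3 members past adjusted over the list alone.

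**Figure D2:**
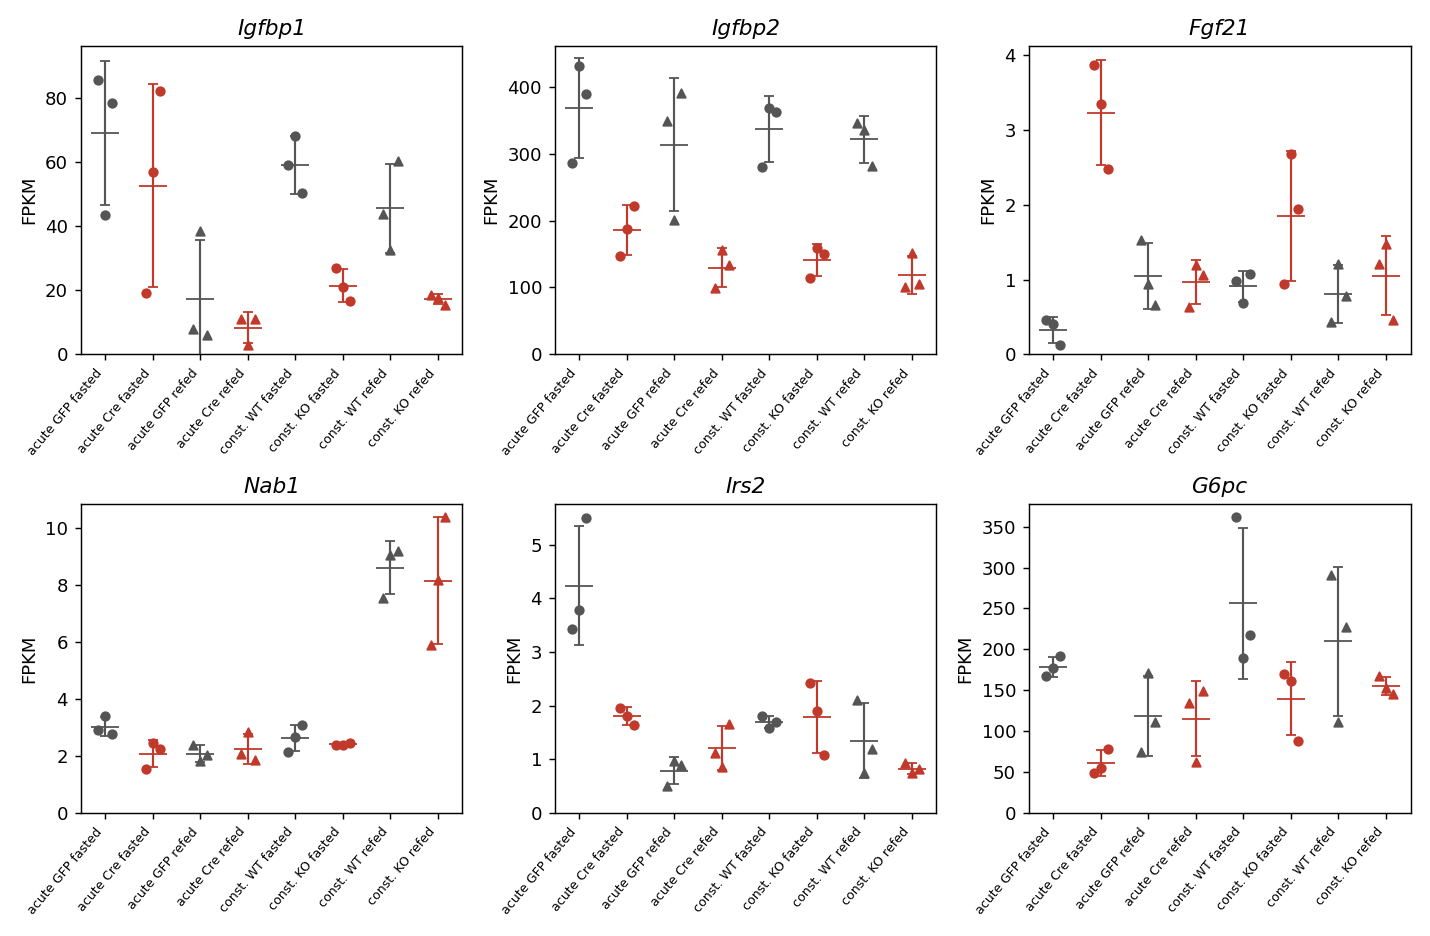
FPKM of Igfbp1, Igfbp2, Fgf21, Nab1, Irs2 and G6pc in each library, circles fasted and triangles refed, grey control and red knockout, with group mean and SD. Fgf21 stands at 3.23 FPKM in fasted acute knockout livers against 0.330 in their controls, and Igfbp2 at 141 against 337 FPKM in fasted constitutive livers.

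Fasted constitutive knockout and wild-type livers were compared to ask what constitutive loss of FoxO1 changes. Igfbp1 (chromosome 11, 7197787 to 7202546) and Igfbp2 (chromosome 1, 72824480 to 72852471), which encode liver-made binding proteins of insulin-like growth factors, fell 2.76-fold, at 21.4 ± 5.14 against 59.1 ± 8.97 FPKM, and 2.39-fold, at 141 ± 24.1 against 337 ± 49.0 FPKM (SD, n = 3 each). The collagen gene Col4a2 (chromosome 8, 11312829 to 11449287) rose 2.19-fold, at 6.57 ± 0.931 against 3.0 ± 0.386 FPKM, and the acetyltransferase gene Nat8 (chromosome 6, 85830387 to 85831890) 2.26-fold, at 13.7 ± 0.947 against 6.05 ± 1.41 FPKM. limma called 10 of 10375 genes, 6 higher and 4 lower, or 6 higher and 9 lower with median-of-ratios scaling.

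On the log2 scale, changes were -1.44 ± 0.21 for Igfbp1 (SE; adjusted p = 0.0267), -1.26 ± 0.18 for Igfbp2 (0.0267), 0.92 ± 0.14 for Col4a2 (0.0428) and 1.08 ± 0.13 for Nat8 (0.0222). The pseudogene Apoo-ps (0.79 ± 0.12), of uncertain level, the glypican Gpc1 (0.69 ± 0.10), the ecto-nucleotidase Nt5e (0.63 ± 0.086) and Bmp5 (0.54 ± 0.074) also rose, and the adrenergic receptor Adrb3 (-0.97 ± 0.15) fell. Apart from Foxo1, 0 of these calls held with any library left out: the call was lost without any of 3 to 6 libraries, KO fasted 1, 2 and 3 included, for Igfbp1, Col4a2, Igfbp2, Nt5e, Nat8, Apoo-ps, Gpc1, Bmp5 and Adrb3 (adjusted p up to 0.206). Counts were 3 without WT fasted 3 and 1, 1 and 1 without KO fasted 1, 2 and 3. Cyp8b1 (-1.01), G6pc (-0.87), Fgf21 (0.54), Pck1 (-0.43), Cyp7a1 (0.081), Ppargc1a (-0.071), Irs2 (0.022) and Srebf1 (0.039) had SE from 0.13 to 0.35 and adjusted p from 0.305 to 0.9995.

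Of 16 lists past the test in fasted constitutive livers, 0 passed with estimated correlation. Lipoprotein and lipid export genes were lower (14 of 20 below 0, median -0.14, adjusted p = 4.24e-05, p = 0.0938 with estimated correlation), with Scarb1 (-0.56) and Apom (-0.56) lower adjusted over the list alone. Gluconeogenic genes were lower (11 of 13 below 0, median -0.12, adjusted p = 4.24e-05, p = 0.0938 with estimated correlation), with Slc37a4 (-0.50) and Got1 (-0.59) lower adjusted over the list alone. FoxO1 targets were lower (12 of 17 below 0, median -0.10, adjusted p = 0.00436, p = 0.302 with estimated correlation), with Igfbp1 called and Apom beside it adjusted over the list alone. Insulin and IGF signalling genes were lower (8 of 14 below 0, median -0.076, adjusted p = 0.00321, p = 0.0938 with estimated correlation). Igfbp1 and Igfbp2 were called, the same 2 passed adjusted over the list alone, and the result was lost without KO fasted 1 (0.0552). Bile acid genes were lower (8 of 12 below 0, median -0.088, adjusted p = 0.00315, p = 0.235 with estimated correlation). Cyp8b1 and Cyp27a1 (-0.37) were lower adjusted over the list alone, and the result was lost without WT fasted 1 (0.0506). Immediate early genes were higher (8 of 10 above 0, median 0.28, adjusted p = 0.00231, p = 0.146 with estimated correlation), Junb (1.01) and Egr1 (0.70) adjusted over the list alone. PPARα targets were higher (18 of 24 above 0, median 0.14, adjusted p = 0.00231, p = 0.434 with estimated correlation), lost without WT fasted 1 or KO fasted 3 (0.0565 to 0.0962). Endothelial markers were higher (8 of 8 above 0, median 0.35, adjusted p = 2.27e-08, p = 0.0938 with estimated correlation). In all, 4 were higher adjusted over the list alone, among them Clec4g (0.47) and Eng (0.42). Kupffer cell markers (7 of 8 above 0, median 0.37, adjusted p = 0.00946, p = 0.451 with estimated correlation; lost without WT fasted 1 or KO fasted 1 (0.115 to 0.737)) and stellate cell markers (7 of 7 above 0, median 0.24, adjusted p = 0.0177, p = 0.427 with estimated correlation; lost without WT fasted 2 or KO fasted 1 (0.0989 to 0.355)) were higher too.

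Periportal, heat shock, cholesterol synthesis and urea cycle genes were lower and female-biased and interferon response genes higher in fasted constitutive knockout livers (adjusted p from 0.0109 to 0.0488, or p from 0.0954 to 0.647 with estimated correlation). None of their members passed over all genes or adjusted over the list alone. Each was lost without some library: periportal without KO fasted 1 (0.115), heat shock without WT fasted 3 or KO fasted 1 (0.222 to 0.243), cholesterol without WT fasted 1 or 3 or KO fasted 1 or 3 (0.0690 to 0.744), urea cycle without WT fasted 2 or KO fasted 1 or 2 (0.141 to 0.453), female-biased without WT fasted 1 or 3 or KO fasted 2 (0.0850 to 0.125) and interferon without WT fasted 1, 2 or 3 or KO fasted 1 or 2 (0.0510 to 0.276).

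Refed constitutive livers were compared in the same way. Igfbp2 fell 2.70-fold, at 119 ± 28.5 against 321 ± 34.8 FPKM (SD, n = 3 each), with a log2 change of -1.45 ± 0.18 (SE; adjusted p = 0.0173). The cytochrome P450 Cyp2c37, one of several near-identical genes (chromosome 19, 39992424 to 40012243), fell 2.96-fold, at 36.7 ± 7.88 against 109 ± 16.4 FPKM (-1.55 ± 0.20, 0.0236). With Foxo1 these were the 3 genes of 10375 that limma called, all lower, against 1 higher and 4 lower with median-of-ratios scaling. The call was lost without any of 3 to 4 libraries, WT refed 1 and KO refed 3 included, for Cyp2c37 and Igfbp2 (adjusted p up to 0.0882), and counts were 5 without WT refed 3 and 13 without KO refed 1. Igfbp1 stood at 17.1 ± 1.56 against 45.6 ± 13.9 FPKM (-1.32 ± 0.21, adjusted p = 0.0637) and Cyp8b1, the sterol hydroxylase that sets bile acid composition, at 87.1 ± 23.4 against 189.7 ± 40.4 FPKM (-1.13 ± 0.25, 0.162). Ppargc1a (-0.30), Irs2 (-0.32), Srebf1 (0.40), Pck1 (-0.29), Cyp7a1 (-0.30), G6pc (-0.33) and Fgf21 (0.17) had SE from 0.13 to 0.35 and adjusted p from 0.453 to 0.805.

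Bile acid genes were lower in refed constitutive knockout livers (11 of 12 below 0, median -0.25, adjusted p = 0.000475, p = 0.376 with estimated correlation). Adjusted over the list alone 5 were lower, including Cyp8b1, Cyp27a1 (-0.39) and Abcb11 (-0.24). Pericentral genes were lower (9 of 11 below 0, median -0.18, adjusted p = 0.00338, p = 0.514 with estimated correlation). In all, 3 were lower adjusted over the list alone, among them Cyp2e1 (-0.50) and Glul (-0.35). FoxO1 targets were lower (12 of 17 below 0, median -0.28, adjusted p = 0.00716, p = 0.536 with estimated correlation), with Igfbp1 and Apom lower adjusted over the list alone. Female-biased genes were higher (6 of 6 above 0, median 1.27, adjusted p = 0.000475, p = 0.376 with estimated correlation). In all, 3 were higher adjusted over the list alone, among them Cyp17a1 (1.34) and Acot3 (1.58). Male-biased genes were lower (10 of 13 below 0, median -0.26, adjusted p = 0.00687, p = 0.578 with estimated correlation), with Cyp2d9 (-0.64) adjusted over the list alone, lost without WT refed 2 or KO refed 2 (0.0770 to 0.0802). Fatty acid synthesis genes (15 of 16 above 0, median 0.16, adjusted p = 0.00338, p = 0.536 with estimated correlation; lost without WT refed 2 or KO refed 1 (0.0546 to 0.134)) and cholesterol synthesis genes (20 of 21 above 0, median 0.20, adjusted p = 0.00437, p = 0.766 with estimated correlation; lost without KO refed 1 (0.220)) were higher, with 0 members past adjusted over either list alone. In these 7 lists 0 members were called over all genes.

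Refeeding of wild-type livers gave the response to food in constitutive controls. The lipogenic gene Thrsp (chromosome 7, 97412957 to 97417510) rose 2.05-fold, at 949 ± 134 against 462 ± 126 FPKM (SD, n = 3 each), the calcineurin regulator Rcan1 (chromosome 16, 92391953 to 92466146) 2.89-fold and the transcriptional repressor Nab1 (chromosome 1, 52455849 to 52500448) 3.28-fold. Hal (chromosome 10, 93488768 to 93516743) fell 1.59-fold, at 80.6 ± 5.98 against 128 ± 15.7 FPKM. limma called 33 of 10375 genes, 16 higher and 17 lower, or 29 higher and 53 lower with median-of-ratios scaling. Counts were 16 and 9 without WT fasted 1 and 2 and 1 without WT refed 3.

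Log2 changes came to 1.07 ± 0.18 for Thrsp (SE; adjusted p = 0.0368), 1.39 ± 0.19 for Rcan1 (0.0132), 1.41 ± 0.16 for Nab1 (0.00721) and -0.66 ± 0.10 for Hal (0.0256). Fmo2 (1.48 ± 0.25), the adaptor Shb (0.85 ± 0.11) and the chaperone Dnajb9 (0.81 ± 0.14) rose. The kinase Sgk2 (-0.94 ± 0.12), Gtf2ird1 (-0.90 ± 0.14), Eepd1 (-0.88 ± 0.15), Slc24a6, now Slc8b1 (-0.78 ± 0.14) and Tcp11l2 (-0.75 ± 0.13) fell. Apoo-ps fell from 2.36, 3.49 and 2.72 FPKM to values under 0.001 in the 3 refed libraries (adjusted p = 1.55e-05), the one call that held with any library left out. Its level is uncertain, since its reads can be those of Apoo and it ran from 0.000782 to 11.1 FPKM among fasted and 0.256 to 17.5 among refed acute controls. The others were lost without WT refed 3 for Rcan1, Nab1, Shb and Sgk2 (adjusted p up to 0.0560) and without any of 4 to 5 libraries, WT refed 3 included, for Thrsp, Hal, Dnajb9, Fmo2, Gtf2ird1, Eepd1, Slc24a6 and Tcp11l2 (p up to 0.162). Cyp7a1 (1.28), Igfbp1 (-0.40), Irs2 (-0.24), Srebf1 (0.28), G6pc (-0.34), Cyp8b1 (-0.24), Ppargc1a (-0.11), Foxo1 (0.077), Fgf21 (-0.10) and Pck1 (0.013) had SE from 0.13 to 0.35 and adjusted p from 0.0722 to 0.984.

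Ribosome biogenesis genes rose in refed wild-type livers (14 of 15 above 0, median 0.34, adjusted p = 9.29e-08, p = 0.543 with estimated correlation). None was called, and 9 were higher adjusted over the list alone, led by Nolc1 (0.73). Heat shock genes rose (7 of 8 above 0, median 0.47, adjusted p = 0.000472, p = 0.559 with estimated correlation), with 0 called and 6 adjusted over the list alone. PPARα targets were lower (22 of 24 below 0, median -0.19, adjusted p = 1.33e-05, p = 0.543 with estimated correlation). No member was called, and the lipid droplet gene Plin2 (-0.65) passed adjusted over the list alone. Periportal genes were lower (8 of 10 below 0, median -0.14, adjusted p = 0.0102, p = 0.331 with estimated correlation), with Hal called and 3 adjusted over the list alone. Acute phase genes (10 of 11 above 0, median 0.30, adjusted p = 0.00653, p = 0.543 with estimated correlation; lost without WT fasted 3 or WT refed 2 (0.0728 to 0.123)) and immediate early genes (8 of 10 above 0, median 0.19, adjusted p = 0.0402, p = 0.543 with estimated correlation; lost without WT fasted 2 or 3 or WT refed 2 (0.0583 to 0.163)) were higher. None was called, and Dusp1 (1.47) alone passed adjusted over the list alone. Kupffer cell markers were higher (8 of 8 above 0, median 0.38, adjusted p = 0.0123, p = 0.654 with estimated correlation), with 0 members past either way, lost without WT fasted 1 (0.436). With an estimated correlation 0 of these 7 lists passed.

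Refeeding of constitutive knockout livers gave the response to food in constitutive absence of FoxO1. Thrsp rose 2.79-fold, at 1231 ± 97.3 against 442 ± 52.8 FPKM (refed against fasted; SD, n = 3 each). Plin2 (chromosome 4, 86656565 to 86670059) fell 1.92-fold, at 185 ± 12.4 against 355 ± 43.2 FPKM, and the thioredoxin-binding protein gene Txnip (chromosome 3, 96557957 to 96561857) 2.50-fold, at 14.5 ± 1.83 against 36.3 ± 5.99 FPKM. limma called 589 of 10375 genes, 207 higher and 382 lower, or 391 higher and 435 lower with median-of-ratios scaling. Counts were 71, 95 and 269 without KO fasted 1, 2 and 3 and 316 and 86 without KO refed 1 and 2.

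Log2 changes were 1.48 ± 0.18 for Thrsp (SE; adjusted p = 0.00306), -0.93 ± 0.12 for Plin2 (0.00448) and -1.26 ± 0.18 for Txnip (0.00690). Fmo2 (1.60 ± 0.25), Rcan1 (1.57 ± 0.19), Cib3 (1.91 ± 0.39) and Tsku (1.49 ± 0.31) rose. Arrdc3 (-1.47 ± 0.32), Tymp (-1.56 ± 0.23) and Sco2 (-1.25 ± 0.24) fell, the last 2 overlapping and uncertain. Apoo-ps fell from 4.76, 5.76 and 6.45 FPKM to under 0.001 refed (adjusted p = 3.12e-07). The microRNA Mir719 was lower, at 17.4, 0.00138 and 0.000362 against 60.3, 24.2 and 40.5 FPKM. Its level is uncertain (0 to 178 FPKM in Cre fasted). The call was lost without KO fasted 1 for Klf9 (adjusted p up to 0.0653), without KO fasted 1 or KO refed 1 for Cib3 (p up to 0.0578), without KO fasted 1 or KO refed 2 for Nop2 (p up to 0.0586) and without any of 3 to 6 libraries, KO fasted 1 and 2 and KO refed 2 included, for Tsku, Bag3, Arrdc3, Sco2, Mir719, Acacb, Cpt2, Dnajb9, Hspa1b, Susd4, Kdm5d and Zbtb16 (p up to 0.176). Cyp7a1 (0.90), Irs2 (-0.59), Ppargc1a (-0.34), Srebf1 (0.64), Fgf21 (-0.47), Cyp8b1 (-0.36), Igfbp1 (-0.28), Pck1 (0.15), G6pc (0.21) and Foxo1 (-0.017) did not pass (SE from 0.13 to 0.35 and adjusted p from 0.0818 to 0.946).

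PPARα targets fell in refed constitutive knockout livers (24 of 24 below 0, median -0.29, adjusted p = 4.02e-07, p = 0.610 with estimated correlation). Of these 3 were called, among them Plin2 and Cpt2 (-0.25), and 13 were lower adjusted over the list alone. Ribosome biogenesis genes rose (13 of 15 above 0, median 0.30, adjusted p = 7.16e-07, p = 0.610 with estimated correlation), and 6 were called and 9 passed adjusted over the list alone, among them Nolc1 (0.94) and Nop2 (0.74). Heat shock genes rose (7 of 8 above 0, median 0.50, adjusted p = 0.000936, p = 0.610 with estimated correlation). Bag3 (0.72) and Hspa1b (0.74) were called, and 6 passed adjusted over the list alone. Cholesterol synthesis genes were higher (18 of 21 above 0, median 0.38, adjusted p = 0.000936, p = 0.626 with estimated correlation), with 0 members past either way. Fatty acid synthesis genes were higher (13 of 16 above 0, median 0.27, adjusted p = 0.00568, p = 0.610 with estimated correlation). Thrsp and Acacb (0.60) were called, and 3 passed adjusted over the list alone. Unfolded protein response genes were higher (14 of 15 above 0, median 0.21, adjusted p = 0.00447, p = 0.610 with estimated correlation), with Dnajb9 (0.56) called over all genes and adjusted over the list alone. Glucocorticoid-responsive genes were higher as a list (8 of 10 above 0, median 0.47, adjusted p = 0.0213, p = 0.610 with estimated correlation). Zbtb16 (1.19) was up and Klf9 (-0.93) down over all genes, and 6 were up and 1 down adjusted over the list alone. The result was lost without KO fasted 1 or 2 or KO refed 3 (0.0626 to 0.113) and with scaling (0.0522). Male-biased genes were lower (12 of 13 below 0, median -0.34, adjusted p = 0.0261, p = 0.610 with estimated correlation). Kdm5d (-0.57) and Susd4 (-0.83) passed over all genes and adjusted over the list alone, and the result was lost without KO fasted 3 or KO refed 2 (0.0843 to 0.169). With an estimated correlation 0 of these 8 lists passed.

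For the knockout by refeeding interaction of the constitutive model limma called 0 of 10375 genes, and 457 had an unadjusted p under 0.05. The count was 1 without WT refed 2 and 1 without KO refed 1. Cholesterol synthesis genes had a higher refeeding change in the knockout (20 of 21 above 0, median 0.36, adjusted p = 1.51e-05, p = 0.631 with estimated correlation), and endothelial markers a lower one (8 of 8 below 0, median -0.27, adjusted p = 0.00251, p = 0.625 with estimated correlation), with 0 members past over all genes or adjusted over either list alone.

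To ask whether acute and constitutive deletion differ, their effects were compared in a fit of all 24 libraries. limma called 0 of 10682 genes in either state, with 839 genes at an unadjusted p under 0.05 fasted and 1165 refed. Fasted counts were 45 without GFP fasted 2 and 29 without Cre fasted 1, and 4 without the 4 deeper libraries, and refed counts were 14 without GFP refed 1, 1 without Cre refed 2 and 2 without WT refed 1. Endothelial markers had a lower change in the acute than in the constitutive fasted livers (8 of 8 below 0, median -0.87, adjusted p = 1.49e-09, p = 0.319 with estimated correlation). Adjusted over the list alone 7 were lower, led by Oit3 (-1.52).

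In refed livers, male-biased genes had a higher change in the acute model (13 of 13 above 0, median 1.78, adjusted p = 5.12e-08, p = 0.198 with estimated correlation). In all, 7 were higher adjusted over the list alone, for example Cyp2d9 (1.78). Female-biased genes had a lower change (5 of 6 below 0, median -2.88, adjusted p = 6.54e-05, p = 0.198 with estimated correlation). Adjusted over the list alone 5 of 6 were lower, for example Cyp17a1 (-2.79). Bile acid genes had a higher change (11 of 12 above 0, median 0.23, adjusted p = 0.00731, p = 0.198 with estimated correlation), with Abcb11 and Cyp7b1 past adjusted over the list alone. PPARα targets had a lower change (19 of 24 below 0, median -0.10, adjusted p = 0.00292, p = 0.598 with estimated correlation). Vnn1 (-1.11) and Acot1 (-1.17) passed adjusted over the list alone, and the result was lost without the deeper libraries (0.0723). In both states 0 members of any list passed over all genes.

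Overlaps of calls were tested with Fisher's exact test in a family of 19, across genes, which are not independent replicates. The one gene called lower in both models, fasted or refed, was Foxo1, which the design deleted, and 0 genes rose in both. Besides Foxo1, Cyp2b10 in the acute and Igfbp2 in the constitutive model fell in both states, while Gm4956 fell in fasted (-0.98 ± 0.17; lost without GFP fasted 2 or 3 or Cre fasted 2 or 3, adjusted p up to 0.154, and over the shallower libraries, 0.105) and rose in refed (1.75 ± 0.17) acute knockout livers. In the acute model Igfbp2, chosen after its values were seen, was lower in each knockout than in each control library of the same state, by -0.98 ± 0.26 fasted (adjusted p = 0.154) and -1.24 ± 0.26 refed (0.113), and did not pass. Its change did not differ detectably between models (0.27 ± 0.34, adjusted p = 0.913, and 0.21 ± 0.34, 0.851). Refeeding of controls raised 7 genes in both models (0.724 expected of independent lists, adjusted p = 7.27e-06) and lowered 8 (0.283 expected, 3.54e-10). Calls at 0.01 were too few to judge this (1 rising and 1 falling in constitutive controls). Acute control and knockout livers shared 210 rising (21.6 expected) and 52 falling genes (2.10). Constitutive ones shared 13 (0.319) and 15 (0.626). Lists of 1 model shared spread estimates, acute ones also a median rise of all genes (0.077), so expected counts may be too low.

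Refeeding genes called in the controls of one model were then measured in the other model. The 494 genes that rose in acute controls had a median log2 change of 0.20 in constitutive wild type and 0.22 in constitutive knockout livers, and the 181 that fell had -0.30 and -0.37. The 15 genes that rose in constitutive controls had 0.74 in acute control and 0.56 in acute knockout livers, and the 16 that fell had -0.67 and -0.46. In none of the 4 sets did limma's fry test find a difference between knockout and control (adjusted p from 0.471 to 0.871 over these 4 tests).

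**Figure D3:**
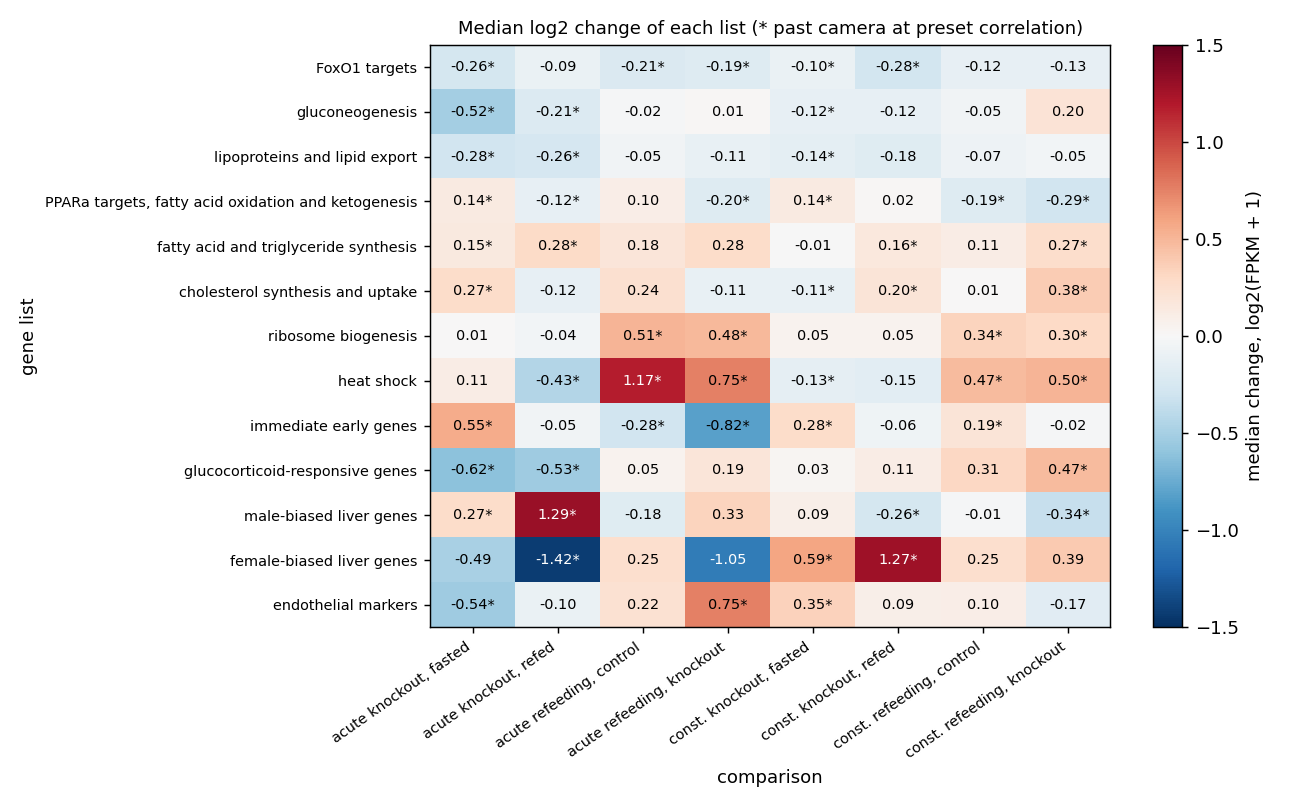
Median log2 change of 13 gene lists in the 8 knockout and refeeding comparisons, coloured from low to high, with a star where the list passed limma's camera at the preset correlation. Ribosome biogenesis and heat shock genes are higher in each of the 4 refeeding comparisons, and lipoprotein genes are lower in the 4 knockout comparisons, with a star in 3.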

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

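The interactions and the differences of knockout effects between models were fixed before the data were examined. All tests of explanations, results over the shallower libraries, splits of the libraries and differences of refeeding effects between models were chosen after seeing the data, those on single libraries and depth for the male-biased and endothelial lists before their own results. Results stand here where a test of the difference between knockout and control or between models passed. Bracketed entries after a semicolon name the libraries whose omission, 1 at a time, ended the call, with the adjusted p then. Chance could not be judged from the splits of the pairwise comparisons, since 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 31, 11, 686 and 569 genes in the acute model and 10, 3, 33 and 589 in the constitutive one, each the highest of its 10, and the highest other gave 3, 1, 4, 0, 0, 2, 1 and 0.

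In refed acute knockout livers the male-biased list was higher and the female-biased list lower, the reverse of refed constitutive livers, and the model difference passed for both (adjusted p = 5.12e-08 and 6.54e-05, or p = 0.198 for both with an estimated correlation). Animals of both sexes in the refed acute groups are argued against by Xist and Ddx3y, since 0 of 6 libraries had Xist at an FPKM of 1 or more or Ddx3y under 1. For the male-biased list a single library is argued against by a median change of 1.08 without GFP refed 3, the value nearest 0, and depth by 1.24 over the shallower libraries, against 1.29. For the female-biased list dependence on a single library or on the deeper ones stays open. Its median moved from -1.42 to -1.17 without GFP refed 2 and -1.06 over the shallower libraries. Its call was lost with fewer libraries (adjusted p = 0.134 and 0.191). Other differences between animals of the groups were not tested and stay open.

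Endothelial markers were lower in fasted acute knockout livers, and their change differed from the constitutive one (adjusted p = 1.49e-09, or p = 0.319 with an estimated correlation). A single library is argued against by a median of -0.423 without Cre fasted 3, the value nearest 0. The shallower libraries gave -0.594. Fewer cells of every kind but hepatocytes cannot be told apart from an endothelial change, because endothelial markers moved by -0.454 against Kupffer and stellate markers (SE 0.226, 95% interval from -0.975 to 0.0672). A change in endothelial cells after loss of FoxO1 was not tested and stays open.

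For the acute interaction, Gm4956, Prelid2 and Snord17 had differences of 2.73, 3.28 and 2.21 on the log2 scale. Over the shallower libraries the lowest was 2.38, and Prelid2 (adjusted p = 0.163) and Snord17 (0.227) did not pass with fewer libraries. Prelid2 and Gm4956 spread widely within constitutive groups (percentile 99.2 and 98.6 of 500 genes of like level). Whether such spread could give these differences was not tested. Snord17 (221 bases) lies near the floor, at 0 in 6 of 12 constitutive libraries. Of 100 splits 2 gave 3 genes or more, but 1 of these, with 3 of the 4 deeper libraries together, gave 307, which points to structure in the samples, so the splits do not settle chance.

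In that interaction cholesterol synthesis genes were also lower (adjusted p = 0.00121, 0.0990 over the shallower libraries; GFP fasted 3 or GFP refed 2 (0.211 to 0.226)) and endothelial markers higher (0.00728, 0.0773 over the shallower libraries; GFP fasted 1 or 3, Cre fasted 3 or Cre refed 1 (0.0636 to 0.0873)), with p = 0.783 and 0.730 with an estimated correlation. PPARα targets (4.39e-12), immediate early (9.78e-05) and heat shock genes (0.000112) were lower (p = 0.164, 0.462 and 0.462 with an estimated correlation). In the constitutive interaction, cholesterol synthesis (1.51e-05) and fatty acid synthesis genes (0.00222; WT refed 2 (0.0553)) were higher and endothelial markers lower (0.00251), as were pericentral (0.0130; WT fasted 3 or KO refed 2 (0.0566 to 0.0772)), male-biased (0.0136; WT fasted 2, KO fasted 3, WT refed 2 or KO refed 2 (0.0581 to 0.332)), immediate early (0.0219; WT fasted 3, KO fasted 2 or WT refed 2 (0.0772 to 0.0871)) and PPARα genes (0.0408; WT fasted 1 or 3, KO fasted 2 or 3, WT refed 1 or 3 or KO refed 2 (0.0611 to 0.245)), while unfolded protein response genes were higher (0.0190; WT fasted 2 or 3, KO fasted 1 or 2, WT refed 2 or KO refed 2 (0.0530 to 0.648)). With an estimated correlation p ran from 0.625 to 0.656. With 0 genes called all 100 splits gave as many, at most 4, and cannot judge chance.

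The model difference called 0 genes, so all 100 splits gave as many in each state, at most 1 fasted and 13 refed, and cannot judge chance. Fasted, the acute change was higher for cholesterol synthesis (0.000135, 0.107 over the shallower libraries; GFP fasted 3 (0.123)), immediate early (0.0193; GFP fasted 2 or 3, Cre fasted 3 or WT fasted 3 (0.0551 to 0.281)), male-biased (0.0203; GFP fasted 1, Cre fasted 1 or 2, WT fasted 3 or KO fasted 1 (0.0608 to 0.173)), fatty acid synthesis (0.0469; GFP fasted 2 or 3, Cre fasted 1 or 2, WT fasted 3 or KO fasted 1 or 3 (0.0601 to 0.159)), oxidative stress (0.0498; GFP fasted 1, 2 or 3, Cre fasted 1, 2 or 3, WT fasted 2 or 3 or KO fasted 3 (0.0569 to 0.161)) and heat shock genes (0.0498; GFP fasted 1, 2 or 3, Cre fasted 1, 2 or 3, WT fasted 2 or 3 or KO fasted 1 (0.0561 to 0.234)). It was lower for clock (0.00900) and glucocorticoid genes (0.0203; GFP fasted 3, Cre fasted 1 or 2 or KO fasted 3 (0.0569 to 0.178)). With scaling, male-biased (0.0512), fatty acid (0.0608), oxidative stress (0.0506) and heat shock genes (0.0804) did not pass, nor did fatty acid (0.222) and glucocorticoid genes (0.122) over the shallower libraries. Refed, it was higher for bile acid (0.00731) and oxidative stress genes (0.0375; GFP refed 2 or 3, Cre refed 2, WT refed 1 or KO refed 2 or 3 (0.0589 to 0.205)) and lower for PPARα (0.00292), cholesterol synthesis (0.0127; GFP refed 2, Cre refed 1 or KO refed 1 (0.116 to 0.517)), glucocorticoid (0.0128; GFP refed 2, Cre refed 2 or KO refed 3 (0.125 to 0.183)) and heat shock genes (0.0304; GFP refed 1, Cre refed 2 or 3, WT refed 2 or KO refed 3 (0.0537 to 0.479)). With an estimated correlation p ran from 0.319 to 0.697 fasted and from 0.198 to 0.987 refed.

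For refeeding effects limma called 1 gene to differ between models in controls, Nab1 (log2 difference -1.80 ± 0.22, adjusted p = 0.0013), which rose from 2.62 to 8.60 FPKM in constitutive and stood at 3.02 and 2.08 FPKM in acute livers. The count was 3 without GFP fasted 3 or GFP refed 2, and 6 of 100 splits gave 1 gene or more, at most 3, so chance is not excluded for a count of 1. In knockouts 27 genes differed, Nab1 among them (-1.32 ± 0.22, adjusted p = 0.0263; 2.41 to 8.15 FPKM in constitutive and 2.07 to 2.23 in acute livers), 22 higher and 5 lower, or 15 higher and 42 lower with scaling, which moved the median of all genes from 0.109 to 0.0024. The count was 216, 12 and 0 without Cre fasted 1, 2 and 3, 6, 1 and 71 without Cre refed 1, 2 and 3, 0, 10 and 0 without KO fasted 1, 2 and 3 and 11 and 61 without KO refed 2 and 3, and 124 over the shallower acute libraries. The real split alone of 100 gave 27, the smallest share possible, and the highest other gave 0, but the count rests on single libraries.

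In controls the refeeding change was higher in the acute model for PPARα targets (adjusted p = 3.57e-06) and heat shock genes (3.57e-06). It was lower for immediate early (1.04e-05), clock (0.00269), bile acid (0.00707), pericentral (0.00513, 0.198 over the shallower libraries; GFP refed 3 (0.116)), FoxO1 target (0.0145, 0.0661 with scaling; GFP fasted 1, WT fasted 1 or WT refed 1 (0.0647 to 0.0833)) and urea cycle genes (0.0316, 0.262 over the shallower libraries; GFP fasted 3, GFP refed 1 or 3, WT fasted 1 or 3 or WT refed 2 or 3 (0.0595 to 0.207)). Xenobiotic genes had a median of -0.13 but a mean of 0.123 (0.0185, 0.0667 with scaling and 0.0906 over the shallower libraries; GFP fasted 3, GFP refed 2, WT fasted 1 or WT refed 1 (0.0618 to 0.299)). In knockouts it was lower for immediate early (2.09e-09), cholesterol synthesis (3.14e-05) and female-biased genes (0.00500, and 0.0773 with scaling), and higher for endothelial markers (0.000140). With an estimated correlation p ran from 0.185 to 0.549 in controls and from 0.170 to 0.740 in knockouts.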

How the results depend on the processing

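The depth term, the 8 shallower libraries alone and refeeding differences between models were chosen after seeing the data, other alternatives for genes before. Counts are of genes called. With 3 libraries per group and no total depth, the cause of a change was not tested unless its construction shows it: no filter tests more genes, fits of 2 groups and omissions use fewer libraries.

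With a pseudocount of 0.1 the refed constitutive knockout count moved from 3 to 5, and the knockout minus control median of the falling constitutive refeeding genes in the acute model reversed from 0.21 to -0.078. Without a filter, counts were 17 and 6 for the acute knockout, fasted and refed, 451 and 316 for acute refeeding in controls and knockouts, 4 for the fasted constitutive knockout, and 21 and 275 for constitutive refeeding. With median-of-ratios scaling they were 364 for acute knockout refeeding, 5 for the refed constitutive knockout, 82 for wild-type refeeding and 57 for the difference of refeeding effects in knockouts, and 5 lists passed for the fasted model difference in place of 9. Fits of the 2 compared groups gave 3 for the refed acute knockout, 246 and 128 for acute refeeding, 4 and 9 for the constitutive knockout and 10 and 182 for constitutive refeeding. Array weights gave 4 for the fasted model difference and 207 for the refeeding difference in knockouts.

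The depth term gave 856 for acute knockout refeeding, 5 for the acute interaction, 10 and 1 for the model difference, fasted and refed, and 273 for the refeeding difference in knockouts. Without the 4 deeper libraries counts were 6 and 5 for the acute knockout, 215 and 6 for acute refeeding, 6 for the interaction, 4 for the fasted model difference and 124 for the refeeding difference in knockouts. At an adjusted p under 0.01 controls of the models shared 0 refeeding genes, with too few in constitutive controls to judge or to measure in the acute model.

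The replicate numbers were not taken as pairing, since not every same-numbered pair correlated over 0.1, a bar that true pairing could also miss. Deviations of same-numbered libraries from their group means correlated between -0.349 and 0.378 in the acute model (over 0.1 in 5 of 18 pairs; median -0.018, against -0.0148 for other pairs, 14 of 36 over 0.1) and between -0.156 and 0.281 in the constitutive one (8 of 18; 0.0862 against -0.0417, 6 of 36). With the replicate block, counts were 5 for the refed acute knockout, 457 and 306 for acute refeeding, 80 for wild-type refeeding, 1 for the refed model difference and 77 for the refeeding difference in knockouts. The median correlation was 0.35 between deeper acute libraries (above 0 in 6 of 6 pairs), 0.0897 between shallower ones and -0.172 in mixed pairs.

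Leaving out 1 library in turn gave 7 to 37, 3 to 66, 298 to 580, 57 to 430 and 2 to 9 genes for the acute knockout (fasted, refed), refeeding (control, knockout) and interaction. The constitutive ranges were 1 to 7, 2 to 13, 1 to 32, 71 to 739 and 0 to 1. Model differences ranged from 0 to 45 fasted and 0 to 14 refed, and refeeding differences from 1 to 3 in controls and 0 to 216 in knockouts. In all, 6 of 31, 3 of 11, 204 of 686, 52 of 569 and 2 of 3 acute calls held in every such fit, and 1 of 10, 1 of 3, 1 of 33 and 57 of 589 constitutive ones.

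With an estimated correlation 1 list passed in each acute knockout comparison and 0 in each of the others. Over 127 list results, 77 of 81 kept their call with the depth term, 125 of 127 with the block, 116 of 127 with scaling, 65 of 81 without the deeper libraries and 834 of 1020 with a library left out, and 0 reversed. Of the named genes that were called, 145 of 152 stayed called with the lower pseudocount, 140 with scaling, 125 with the block and 85 without a filter, 87 of 149 in fits of 2 groups, 92 of 97 with the depth term, 31 of 97 without the deeper libraries and 521 of 930 with a library left out, and 0 reversed.

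Reversals of sign occurred among log2 changes that were not called. Without the deeper libraries these were Igfbp1 in the fasted acute knockout (0.16), Srebf1 in acute control refeeding (0.0022) and Ppargc1a in acute knockout refeeding (0.10), and with the lower pseudocount the fasted model difference of Foxo1 (-0.12). With a library left out, log2 changes in the fasted acute knockout ran from -0.98 to 0.040 for Igfbp1 and -0.26 to 0.023 for Srebf1. Refed, they were -0.35 to 0.33 for G6pc, -1.19 to 0.061 for Igfbp1, -0.18 to 0.12 for Fgf21 and -0.29 to 0.25 for Cyp7a1. For acute refeeding they were -0.16 to 0.16 for Srebf1 and -0.026 to 0.31 for Ppargc1a in controls, and -0.37 to 0.24 for Pck1 and -0.19 to 0.072 for Ppargc1a in knockouts. In the fasted constitutive knockout they were -0.14 to 0.22 for Irs2, -0.078 to 0.14 for Srebf1, -0.24 to 0.020 for Ppargc1a and -0.15 to 0.44 for Cyp7a1. For wild-type refeeding they were -0.057 to 0.16 for Foxo1, -0.63 to 0.062 for G6pc, -0.062 to 0.10 for Pck1, -0.042 to 0.58 for Srebf1, -0.25 to 0.062 for Fgf21 and -0.40 to 0.031 for Cyp8b1. For constitutive knockout refeeding they were -0.064 to 0.013 for Foxo1, -0.094 to 0.38 for G6pc and -0.050 to 0.43 for Pck1, and for the constitutive interaction -0.17 to 0.040 for Foxo1.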
